A study of Arabidopsis thaliana with 2 samples.

How the data were processed

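Polysome loading was measured in suspension cells of Arabidopsis thaliana line T87, collected 1 day and 8 days after transfer to fresh medium, with 1 array with 2 channels for each day. Per the labels' protocols, cell extract was spun through a sucrose gradient collected from the bottom in 8 fractions. Fractions 1 to 3 were pooled as polysomal RNA and fractions 1 to 8 as total RNA. Agilent spike-in RNAs for arrays of this type were added to both pools at collection, the Spike A mix to the polysomal pool and the Spike B mix to a pool that the labels there call nonpolysomal. The design text and the labelling protocol name total RNA as the other pool, so the denominator is not fully settled by the labels. RNA was amplified from an oligo(dT) primer, labelled with Cy5 or Cy3 and hybridised, per the labels' protocols. The design text gives 1 biological replicate, so no spread between cultures could be estimated and no p-value is given.

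The values used are the authors' deposited log10 polysome ratios for 39102 array features on each day. The deposited value table of the series held the same numbers, with a largest difference of 0 between both sources, and the authors' deposited table also lists the difference between days, which equals day 8 less day 1 within 0.001. How the authors computed the ratios from the scanner signals, and whether background or dye corrections were applied, is not given in the sources used here. Signals of single channels and detection flags were not analysed here. No column of per-sample values was left unused (0 columns).

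The log base was settled from the spike-in probes, whose day 1 values on the deposited scale reached 0.925 and -0.838 at both ends with an equimolar probe at 0, spaced as the mixing ratios of the kit are on a log10 scale. The direction of the ratio needed a check, because the labels name total RNA as the molecule of the Cy5 channel but describe it as polysomal. A part divided by the whole should lie below 100%, and on day 1 only 73 of 19714 genes, 0.370%, lay above. Small nucleolar and small nuclear RNAs, which are not translated, had the lowest ratios. Since RNA was amplified from an oligo(dT) primer, these values may not stand for the mature forms. The ratio was therefore read with the polysomal pool as numerator on both arrays, and with total RNA as denominator from the design text. The values do not exclude a denominator of nonpolysomal RNA, under which a percent would be relative to the rest of the mRNA and values above 100% would be possible. Values were converted to log2, and ratios are also given as percent of the denominator.

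Features without signal shared a smooth value that depended on the position on the array. Its median over the negative controls was -0.269 on day 1 and -0.601 on day 8 on the deposited log10 scale, which gives such features an artificial change of -1.10 on the log2 scale. This surface was estimated for each array from the 30 nearest features within 0.04 of the negative-control median, and a feature within 0.006 of it was taken as without signal. That removed 25.4% of the gene probe features on day 1 and 26.6% on day 8. The same rule took 95.1% and 95.8% of the negative controls, and 1.56% and 0.625% of the spike-in features. A filter on signal had been planned before the data were examined. This rule replaced it after the values had been seen, since it needs no channel signals. On simulated arrays of 39102 features it recovered 100% of the features without signal, and it wrongly took 1.45% (day 1) and 1.88% (day 8) of those with signal. The full recovery was set by the simulation, in which features without signal scattered far less than the tolerance. Features with partial signal were not simulated, so the shares of negative controls taken describe the real arrays better.

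Of 37478 distinct gene probes, 25920 carried a locus name in the file, 253 were named through a RefSeq accession and 31 through a symbol. Genes with a conserved upstream open reading frame are named in the file together with the locus of that reading frame, and 14 such probes were given to the main gene, a rule set after the names had been seen. A further 242 probes named several loci and 11018 could not be assigned, and neither set was used for genes. Probe names led to 25430 loci, of which 25356 were found in the RefSeq gene table of assembly TAIR10.1, used for symbols and gene types only. The array design's build is not given in the sources used here, so no coordinates are printed. Repeated spots and different probes of a gene were averaged on the log scale. Signal on both days was found for 19714 loci, of which 560 had at least 2 probes.

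The precision is limited by the number of arrays. The median SD between repeated spots of 23 probes, each printed 10 times, was 0.03 on both days on the log2 scale. The median SD between different probes of a gene was 0.14 on day 1, 0.33 on day 8 and 0.30 for the change. Both describe error within an array and leave out differences between cultures, gradients and labelling reactions.

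The change of a gene is the log2 ratio on day 8 less that on day 1, and a size of at least 2-fold was the rule for counts. Gene lists (22, fixed before the data were examined) were described by the median change of their members relative to the median gene, and by the percentile of that median among 10000 random lists of the same size. A list stands apart here when it lies outside the middle 95%. The random lists were to be matched on signal. They were not matched in the main setting, and were matched on the day 1 ratio as an alternative. On simulated values of 20000 genes, 34 of 500 lists of 40 genes without a shift stood apart, against 217 of 500 with a shift of 0.25 and 457 of 500 with a shift of 0.5 on the log2 scale. Genes are named by a rule fixed before the data were examined: the 12 highest and 12 lowest changes among nuclear genes with a symbol whose probes agree in direction, and for each list the 2 highest members, the 2 lowest and the member nearest the median. The text names some of them.

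Alternatives were no filter, the series value table, centring of each array, thresholds of 1.5-fold and 3-fold, genes with at least 2 agreeing probes, matched random lists and hand-listed loci only. Added after the data were seen were a zero at the median spike-in, a wider tolerance of 0.02 for features without signal, the removal of genes above 100%, and lists pruned of members described as other proteins (4 lists). Changes in total RNA signal, a filter on the brighter probes, the brightest probe of a gene and signal-matched random lists were planned and not run, since channel signals were not used here. Relations with coding length, untranslated regions and GC content were planned and not run, since no annotation of transcripts was used here. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.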

Results

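The study asked how the translational state of T87 cells, a green suspension culture of Arabidopsis thaliana, changed between day 1 and day 8 after inoculation of fresh medium. Each day is represented by 1 array, on which RNA from the polysomal part of a sucrose gradient was compared with RNA from the whole gradient. The polysome ratio of a gene, read so, is the share of its mRNA found in the polysomal fractions. The labels are not of a piece on this, since their sentence on the spike-in RNAs calls the other pool nonpolysomal; in that case each percent would be relative to the mRNA outside polysomes, and the order of genes within a day would hold. Signal on both days was found for 19714 genes. A further 1690 genes had signal only on day 1, 1264 only on day 8, and 2758 on neither. There are no replicates, so none of the differences between days has a replicate check, and all of them describe these 2 arrays.

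On day 1 the median gene had a polysome ratio of 36.0%, and ratios were closely grouped, with quartiles of 32.1% and 39.8%. On day 8 the median was 24.3% and the quartiles were 16.8% and 33.4%, so that the interquartile range on the log2 scale widened from 0.31 to 0.99, 3.18 times as wide. Features without signal, which were left out, lay at -0.89 on day 1 and -2.00 on day 8 on the log2 scale. The first lies in the upper tail of genes. The second lies close to the day 8 median (-2.04), so genes were lost from the middle of that distribution. This can widen the day 8 range, by an amount that was not tested. Protein-coding genes (19389) lay at 36.1% and 24.4%. Small nucleolar and small nuclear RNAs lay lowest on both days. The 10 nucleolar ones, guides of rRNA modification, had medians of 3.62% on day 1 and 2.23% on day 8, and 3 nuclear ones, parts of the spliceosome, had 1.68% and 0.53%. Other non-coding RNAs lay between these and the mRNAs, with medians of 22.4% and 13.7% for 32 long non-coding RNA genes, 12.8% and 7.59% for 5 microRNA genes, and 11.2% and 6.14% for 32 genes of other non-coding RNAs. Transcripts encoded in the mitochondrial genome, which are read by the organelle's own ribosomes, were also low, with a median of 13.8% on day 1 and 5.58% on day 8 over 4 genes. Among them ATMG01080, subunit 9 of the mitochondrial ATP synthase, had 5.77% and 1.50%. RNA was amplified from an oligo(dT) primer, so the values of these non-coding and mitochondrial RNAs may not stand for their mature forms. Across genes, the ratios of both days were related with a Spearman rho of 0.388, which is across genes and not across independent samples.

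**Figure D1:**
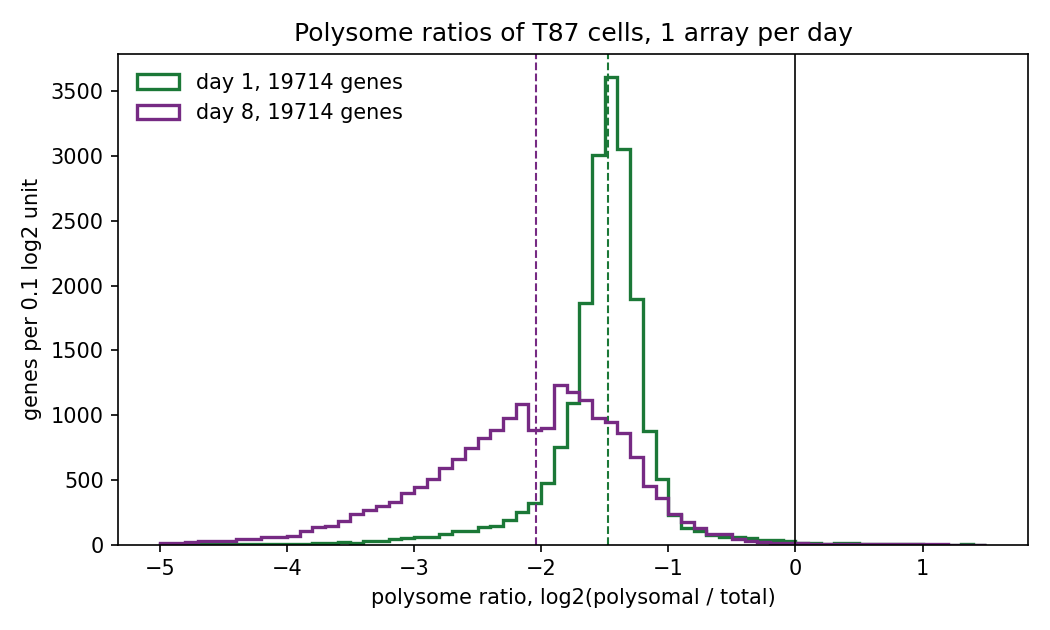
Histogram of polysome ratios of 19714 genes on a log2 axis (polysomal over total as the design text names them, 0 meaning equal amounts), in classes of 0.1, for the day 1 array (green) and the day 8 array (purple), with dashed lines at the medians of 36.0% and 24.3%. The day 8 ratios are lower and more spread out, with a notch near the value of features without signal, which were left out; 11 genes on day 1 and 50 on day 8 lie beyond the axis.

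The comparison of day 8 with day 1 addresses which mRNAs left or entered polysomes as the culture aged. On the deposited scale the ratio was lower on day 8 for 16050 genes (81.4%) and higher for 3635, and the median change was -0.52 on the log2 scale, a ratio of 0.697. At least 2-fold lower ratios were found for 5042 genes and at least 2-fold higher ratios for 238. The position of 0 is open, however, because the 10 spike-in probes themselves had a median change of -0.27, with 9 of 10 below 0 and a range from -0.60 to 0.78. The probe at equal amounts on day 1 changed by -0.01, and the probe next nearest to equal amounts by -0.26. With 0 at the median spike-in, 12859 genes (65.2%) were lower, and 459 genes were at least 2-fold higher and 3259 at least 2-fold lower. Relative to the median gene the counts were 873 and 2130. The higher genes thus made up 4.51% of the genes past 2-fold as deposited, 12.3% from the median spike-in and 29.1% from the median gene. Gene groups are therefore given relative to the median gene, where the choice of 0 plays no part.

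The 12 lowest changes of named genes ranged from -4.82 to -3.41 on the log2 scale. RALFL32, a peptide of the rapid alkalinization factor family, went from 33.4% on day 1 to 2.49% on day 8 (log2 change -3.74). GASA4, a small gibberellin-regulated cysteine-rich protein, went from 38.3% to 3.52% (-3.44). RGP3, a member of the reversibly glycosylated polypeptides, had 89.9% and 5.56% (-4.02), and CKX6, a cytokinin-degrading oxidase, had 85.9% and 6.14% (-3.81). The defensin gene PDF1.2b had 87.7% and 7.73% (-3.50). ARFA1E, a small GTPase of vesicle traffic, had 28.6% and 2.67% (-3.42), and the drought-induced gene DI21 had 15.7% and 1.47% (-3.41). The remaining 5, LBD11, ASL9, NOGC1, AHG1 and XTH21, had day 1 ratios above 100%, from 102% for ASL9 to 136% for LBD11, which a share of total RNA cannot reach.

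The highest change was that of UGT73B2, a flavonoid glucosyltransferase, with 5.04% on day 1 and 81.8% on day 8 (log2 change 4.02). AMT1;5, an ammonium transporter, had 11.5% and 96.4% (3.06), and CPK23, a calcium-dependent protein kinase, had 8.53% and 42.3% (2.31). CP1, a cysteine proteinase, went from 12.1% to 54.1% (2.17), the D-type cyclin CYCD6;1 from 14.9% to 62.4% (2.07), and the zinc-exporting ATPase HMA4 from 10.1% to 41.7% (2.05). PDC3, a pyruvate decarboxylase of ethanolic fermentation, had 18.4% and 75.2% (2.03), and ENODL7, an early nodulin-like protein, had 11.1% and 46.5% (2.06). The other 4, SVL2, LHCB2.1, XW6 and DSEL, had day 8 ratios above 100%, up to 228% for SVL2. All 24 of these genes rest on 1 probe each.

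Of 22 gene lists, 5 stood apart from random lists, against 1.1 expected by chance, and 4 of these 5 lay below the median gene. Standing apart was common among gene groups on these arrays, since 36 of 118 families grouped by description (30.5%) did so, against 22.7% of the lists. mRNAs of cytosolic ribosomal proteins formed the largest of them. Their median ratio was 33.2% on day 1 and 15.9% on day 8, a change of -0.49 relative to the median gene, at percentile 0.00. Of 332 measured members, 262 lay below the median gene and 70 above, and 85 were at least 2-fold lower relative to it. As deposited, 172 were at least 2-fold lower, where 25.6% of all genes were. RPS15A had 27.0% on day 1 and 3.88% on day 8, AT1G15930, of the family that holds ribosomal protein S12e, had 28.9% and 4.34%, and AT3G58700, nearest the list's median, had 32.7% and 16.1%. At the other end, RPL5B had 43.4% and 135%, above the ceiling of a share of total RNA. Translation factors lay at -0.34 (percentile 2.10), with 18 of 30 members below the median gene and 12 above. The 95% bootstrap interval of this median over genes reached 0 (-0.56 to 0.13), unlike those of the other 4 lists that stood apart. TCTP, the translationally controlled tumor protein, had 32.2% and 3.94%, and eEF-1Bb1, a subunit of the elongation factor 1B exchange complex, had 29.7% and 5.07%. The large initiation factor subunits EIF3A, with 41.3% and 67.0%, and EIF4G, with 38.5% and 50.5%, were higher on day 8. The list of translation factors no longer stood apart when features without signal were kept (-0.19, percentile 16.2). It held the same 30 members then. The median gene had moved to -0.67 through features with an artificial change, which shifts the reference and not this list.

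Other parts of the translation machinery did not stand apart. Plastid ribosomal proteins lay at -0.40 (percentile 6.995), with 9 of 11 below the median gene, among them PSRP5 with 32.7% and 12.9%, while PRPL28 had 34.3% and 40.5%. Ribosome biogenesis genes lay at 0.15 (percentile 87.8), with 24 of 40 above. NOP56, a core protein of small nucleolar ribonucleoproteins, had 37.2% on day 1 and 72.8% on day 8, while NOP10, a nucleolar RNA-binding protein, had 27.8% and 6.07%.

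Nuclear genes of the mitochondrial respiratory chain had a median ratio of 32.0% on day 1 and 14.4% on day 8, at -0.51 relative to the median gene (percentile 0.02). Of 43 members, 37 lay below the median gene and 6 above. AT4G37830, a protein related to cytochrome c oxidase, had 32.3% and 5.87%, the ATP synthase subunit gene AT4G29480 had 37.8% and 9.40%, and AT3G62790, a subunit of complex I nearest the list's median, had 25.9% and 12.6%. COX10, which makes heme for the oxidase and is not one of its subunits, was highest with 35.1% and 37.2%. Photosynthesis genes lay at -0.25 (percentile 0.79), with 53 of 70 below the median gene. AT1G76450, of the PsbP family, had 46.9% and 8.79%, LIL3:2, a light-harvesting-like protein, had 34.7% and 6.95%, and PSAE-1, a photosystem I subunit, had 36.5% and 21.3%. LHCB2.1 and LHCB2.2, antenna proteins of photosystem II, stood at the other end with 206% and 190% on day 8. With features without signal kept, the photosynthesis list no longer stood apart (-0.10, percentile 20.4), relative to a median gene that itself had moved to -0.67. The 4 organelle-encoded transcripts had a relative median of -0.80 (percentile 3.38).

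The list above the median gene was glycolysis and fermentation. Its median ratio was 40.6% on day 1 and 39.9% on day 8, at 0.54 relative to the median gene (percentile 99.99), with 19 of 22 members above it. SUS1, a sucrose synthase that cleaves sucrose in sink tissue, had 47.9% and 68.4%, the phosphoglycerate kinase gene PGK had 36.2% and 45.1%, and the aldolase FBA6, nearest the list's median, had 38.0% and 37.9%. GAPC2, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, had 39.6% and 19.1%, and HB1, a class 1 hemoglobin, had 36.8% and 17.3%. Genes of starvation and senescence lay at 0.26 (percentile 93.8), with 15 of 21 above the median gene. DIN10, a dark-induced raffinose synthase family gene, had 32.1% and 38.1%, and TPS11, of the trehalose phosphate synthase family, had 42.5% and 50.4%, while the small protein gene SAG21 had 33.4% and 5.26%. This list stood apart when features without signal were kept (0.38, percentile 98.5), relative to a median gene that itself had moved to -0.67.

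Nutrient lists did not stand apart. Nitrogen uptake and assimilation lay at 0.22 (percentile 89.1), with 16 of 20 above the median gene. GLU1, a ferredoxin-dependent glutamate synthase, had 34.8% and 55.7%, and the nitrate transporter NRT2:1 had 45.0% and 58.7%, while the ammonium transporter AMT1;3 had 56.0% and 28.8%. Phosphate starvation genes lay at 0.12 (percentile 74.2), with 13 of 19 above. PHO2, a regulator of phosphate uptake, had 31.1% and 37.2%, and the galactolipid synthase MGD2 had 29.6% and 7.11%. Of 6 phenylpropanoid and flavonoid genes, 4 lay above the median gene (0.26, percentile 81.9). The ligase 4CL1 had 39.4% and 50.5%, and PAP1, a MYB regulator of anthocyanin synthesis, had 60.1% and 22.5%.

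Genes of DNA replication and the cell cycle did not stand apart as a list (-0.17, percentile 13.0), with 18 of 33 members below the median gene and 14 above. Replication helicase subunits MCM2, with 40.1% on day 1 and 48.0% on day 8, and MCM5, with 35.5% and 41.0%, were at the upper end. The mitotic cyclin CYCB2;1, with 27.8% and 4.15%, and the replication licensing factor CDC6, with 39.9% and 9.23%, were at the lower end. The list depended on the treatment of features without signal: it lay at 0.01 (percentile 52.4) when these were kept, and stood apart at -0.38 (percentile 1.18) with a wider tolerance for them. Core histones lay at 0.08 (percentile 74.7), with 27 of 44 above. The H2A variants HTA11, with 33.3% and 4.92%, and HTA9, with 34.5% and 8.15%, were lowest, and the H2A gene RAT5 was highest with 57.0% and 84.1%.

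Expansins and xyloglucan endotransglucosylases, enzymes and proteins that loosen the cell wall, lay at -0.24 (percentile 2.80), with 25 of 46 members below the median gene. XTH32 had 38.5% and 4.06%, while EXPA1 had 34.4% and 46.1%. The list stood apart only with the wider tolerance (-0.30, percentile 2.22), and lay at -0.15 (percentile 11.6) without genes above 100%. Markers of xylem and secondary walls, another cell type that a culture could form, lay at -0.14 (percentile 27.4), with 7 of 12 below. The fasciclin-like gene FLA11 had 42.0% and 69.8%, and MYB46, a regulator of secondary wall formation, had 35.6% and 9.64%.

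Lists of protein turnover and stress lay near the median gene. The proteasome lay at -0.01 (percentile 44.9; 29 of 63 above), where the ATPase subunit RPT1A had 33.7% and 54.5% and the 20S subunit PBB2 had 33.7% and 12.7%. Autophagy genes lay at 0.01 (percentile 54.0; 14 of 28 above), with AT4G30790, annotated to autophagy, at 37.5% and 64.9% and APG5 at 30.5% and 7.67%. Heat shock proteins lay at -0.01 (percentile 48.1; 34 of 68 above). The chaperone Hsp81.4 had 37.9% and 61.0%, and the small heat shock protein family gene AT5G37670 had 44.7% and 15.2%. Glutathione S-transferases lay at 0.09 (percentile 79.1; 31 of 51 above), with GSTU20 at 12.6% and 20.3% and ATGSTF13 at 32.2% and 9.04%. Late embryogenesis and cold-regulated proteins were at percentile 50.3, with 20 of 39 above. The dehydrin COR47 had 42.7% and 60.4%, and AT2G03740 had 46.7% and 9.04%.

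Genes with a conserved upstream open reading frame were not set apart either (-0.10, percentile 31.8; 7 of 16 above the median gene). The translation of some of them is known to respond to sucrose or polyamines. The sucrose-responsive transcription factor bZIP44 had 30.1% on day 1 and 13.9% on day 8, and BZIP53 had 21.5% and 18.1%. SAMDC, the decarboxylase of polyamine synthesis, had 34.0% and 21.3%, and VTC5, a phosphorylase of ascorbate synthesis, had 37.1% and 7.93%. All 16 were lower on day 8 as deposited, where 81.4% of all genes were. With 0 at the median spike-in change (-0.27), PAO4 (-0.12) and BZIP53 (-0.25) were higher.

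**Figure D2:**
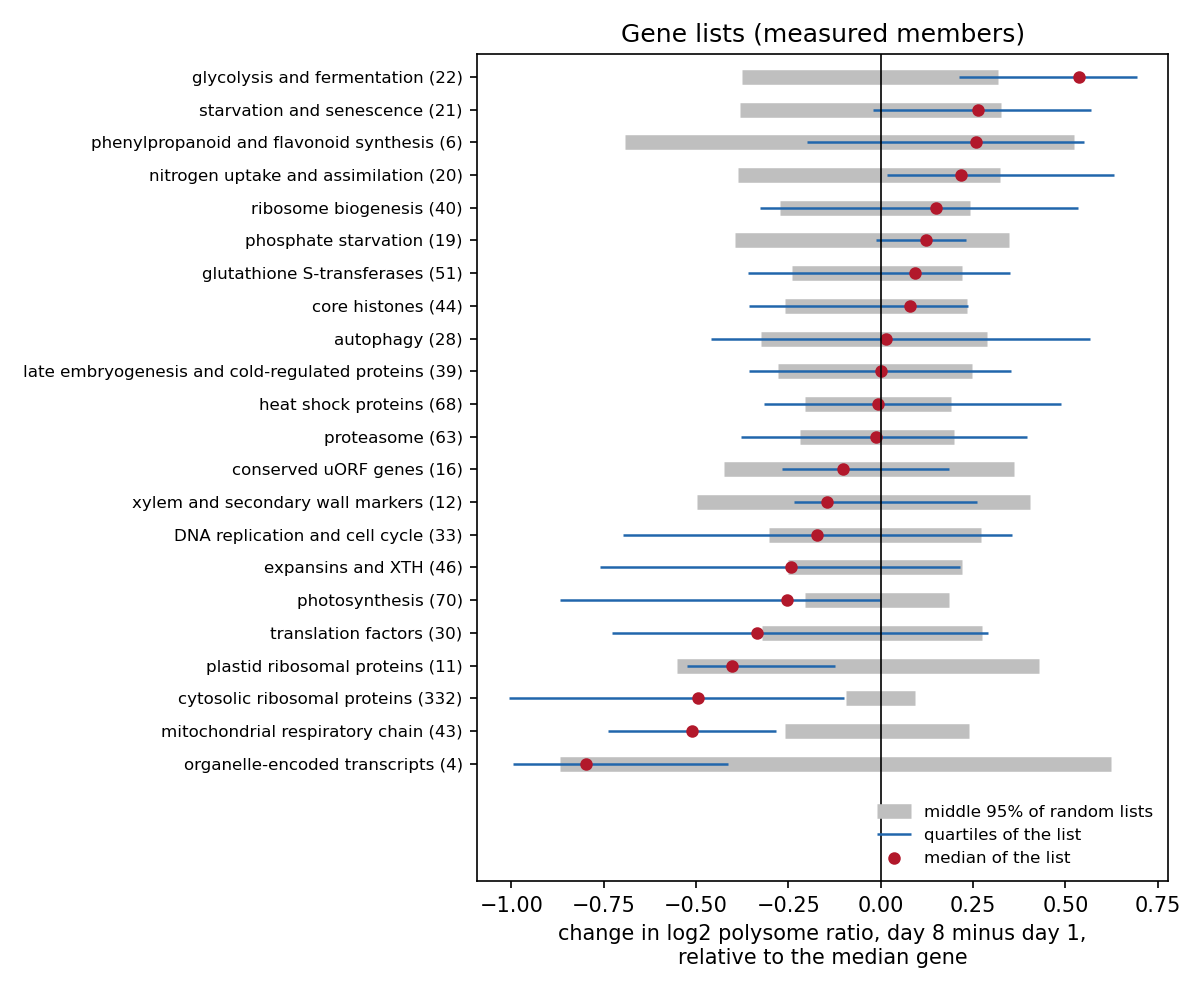
Change in polysome ratio (log2, day 8 less day 1, relative to the median gene) of 22 gene lists, with the number of measured members in brackets; points are list medians, blue lines the quartiles of the members and grey bars the middle 95% of 10000 random lists of the same size. The respiratory chain (-0.51), cytosolic ribosomal proteins (-0.49), translation factors (-0.34) and photosynthesis (-0.25) lie below their grey bars, and glycolysis and fermentation (0.54) lies above.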

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

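The tests on spike-in scaling, repeated spots, the spike-in span, histones and short families, abundant transcripts and eukaryote-type subunits were chosen after the result had been seen; the tests on pairs of probes and on hand-listed loci were written before.

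Probes that the report leaves out carried signal. Of the 11018 unassigned probes, 9323 carried no name but their own identifier (1695 had another name that led to no locus). Of these 9323, 3310 (35.5%) had signal on both arrays, against 2 negative-control features (0.264%), which were used to set the value of no signal. Of named loci, 19714 of 25430 had signal on both arrays. The median ratio of the 3310 probes was 32.7% on day 1 and 22.5% on day 8, with 267 probes at least 2-fold higher and 1007 at least 2-fold lower. Among named genes, whose probes were averaged, 238 of 19714 (1.21%) were at least 2-fold higher and 5042 (25.6%) at least 2-fold lower. Both shares were thus larger among the unnamed probes, most of all that of the higher ones. The control probes eQC-40, eQC-41 and eQC-42, which carry no gene name and are not among the 10 spike-in probes, had signal. They changed by -1.58, 0.57 and 0.51 on the log2 scale. What they bind was not examined. The probe eQC-39, with -0.84, was left out because 9 of its 10 spots were without signal on day 8.

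The lower median ratio on day 8 may be partly a matter of scale. The median change of the spike-in probes, whose proportions were fixed, was -0.27, and the median gene (-0.52) lay within their range of -0.60 to 0.78, with 1 spike-in probe below it. The spike-in probe at equal amounts on day 1 changed little (-0.01), while the probe next nearest to equal amounts changed by -0.26. A real decrease in polysome loading and a scaling difference between the arrays cannot be told apart for the median gene, because each day has 1 array and the spike-in probes disagree. The biological explanation, culture age, was not tested separately.

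The wider spread of ratios on day 8 was set against sources of noise. Variance between repeated spots did not grow, its share of the added variance between genes being -0.000688. The spike-in probes spanned as much on day 1 as on day 8 (1.04 times), so the narrow day 1 distribution did not come with narrow spike-in ratios. This span rests on the 2 end probes. Their RNAs were added when the pools were collected, so the span does not cover the gradient. Over 560 genes with at least 2 probes, the covariance between 2 probes of a gene was larger by 0.43 on day 8 (95% bootstrap interval over genes 0.34 to 0.53; 0.24 on day 1 and 0.67 on day 8). In the same genes the variance of a probe grew by 0.63, against 0.42 between all genes. Of the growth in these genes, 69.1% was shared between probes and the rest was not. The shared part was 0.622 of the variance on day 1 and 0.665 on day 8, so the unshared part grew too. These values argue against spot noise, against compression of the spike-in range, and against single-probe noise as the whole cause. For the shared part, a greater difference in polysome loading between mRNAs on day 8 is 1 hypothesis. A difference between the 2 gradients and dye bias, which the probes of a gene would share, are still open and untested. So is the effect of the features left out near the day 8 median.

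The lower ratios of ribosomal protein mRNAs were weighed against 3 explanations. For list members of other kinds, the hand-listed loci had a relative median of -0.46, with 15 of 25 below the median gene. The 95% interval over these 25 genes reached 0 (-0.88 to 0.08). By the rule written before, that outcome goes with other members as the cause. The interval is also too wide to tell 0 from the list's -0.49. The 86 members described only as eukaryote-type subunits, which organellar ribosomes lack, lay at -0.54 (-0.77 to -0.37). This set was chosen after the result had been seen. Its values argue against other members as the whole cause. Short coding regions stay open: core histones lay at 0.0797, but they were an exception, since 18 of 20 families of short proteins lay below 0 and 4 of them lay as low as the ribosomal protein list (-0.62 to -0.42), among them UPF0497 proteins (-0.47) and the Ole e 1 family (-0.95). Dye bias of abundant transcripts could not be tested without signals. The glycolysis list, of transcripts held to be abundant, lay at 0.54, but its abundance in these cells was not measured. Culture age as the biological explanation stays open too.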

How the results depend on the processing

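The zero at the median spike-in, the wider tolerance, the removal of genes above 100% and the pruning were chosen after the data had been seen; the other alternatives named here were planned. No list that stood apart changed sign. Of 123 alternative values that their construction left free to move, 100 were counted as unchanged: lists by their call, medians within the 95% bootstrap interval over genes, counts within 1.5 times. Another 18 moved further, 3 lists came to stand apart and 2 ceased to. A further 58 values, such as those from the identical value table, could not differ and show no stability. Lists that did not stand apart took the other sign 5 times: with features without signal kept, DNA replication (0.01), proteasome (0.12) and heat shock proteins (0.16), and with the wider tolerance autophagy (-0.08) and heat shock proteins (0.01). No paired analysis was possible because each day has 1 array. With features without signal kept, the median ratio was 37.5% on day 1 and 25.0% on day 8, the median change -0.67 and the number of genes at least 2-fold lower 8846, as follows from the artificial change of such features. Translation factors (-0.19) and photosynthesis (-0.10) then no longer stood apart, and starvation and senescence (0.38) did. These values are relative to the lowered median gene, which raises a list even where its members stay the same, as the 30 translation factors did. The changes of sign in this setting share that shift, so they say little about the lists themselves. With each array centred, the median change was 0 by construction, with 873 genes higher and 2130 lower. With 0 at the median spike-in, the median change was -0.25, with 459 higher and 3259 lower. The threshold of 1.5-fold gave 671 higher and 9135 lower, and 3-fold gave 66 and 1891. The 401 genes with at least 2 agreeing probes had a median change of -0.67, with 10 higher and 129 lower. These values cannot be set directly against those of all genes. Fewer genes were counted, and the rule of agreeing direction drops genes near 0, which by itself moves the median and the shares past 2-fold. The wider tolerance gave a day 8 median of 23.4% and set apart DNA replication and cell cycle (-0.38) and expansins (-0.30). The first then counted 32 members instead of 33, and expansins 43 instead of 46, so the loss of few members went with these calls. Beyond this the cause was not tested. Matching random lists on the day 1 ratio changed none of 22 list calls (expansins then at percentile 8.40), nor did removing genes above 100%; hand-listed loci changed none of the 3 lists that they alter, and pruning none of 4. A stricter signal filter, the brightest probe and signal-matched lists were not run, and signal over background is unknown here. Centring gives no ratio per day.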

Other observations

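The family descriptions, the grouping by protein size and its test were all chosen after the values had been seen. Genes were also grouped by the family description in the authors' deposited table. Of 118 families with at least 15 measured genes, 36 lay outside the middle 95% of random lists, against 5.9 expected by chance. Families of immune receptors had high ratios on day 8. All 17 CC-NBS-LRR disease resistance genes lay above the median gene, with a median of 40.4% on day 1 and 43.3% on day 8 (0.55 relative to the median gene), and so did 40 of 44 TIR-NBS-LRR genes, with 36.2% and 36.3% (0.53). Receptor kinases with S-locus lectin domains (0.65, 11 of 15 above) and those described as leucine-rich receptor-like kinases (0.61, 14 of 17) were also high. The larger family described as leucine-rich repeat protein kinases was less so (0.26, 59 of 87). AAA-type ATPases (0.50, 14 of 19) and ARM repeat proteins (0.31, 70 of 98) were high as well.

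At the low end, the Pollen Ole e 1 and extensin family, mostly small secreted wall proteins, had a median of 37.4% on day 1 and 13.9% on day 8 (-0.95 relative to the median gene; 14 of 16 below). Heavy metal transport and detoxification proteins (-0.47; 22 of 32 below), lipid-transfer proteins (-0.43; 34 of 45 below), Sm-type small nuclear ribonucleoproteins (-0.38; 18 of 22 below) and thioredoxins (-0.35) lay low as well. Families not known for short proteins were low too, such as NAD(P)-linked oxidoreductases (-0.46; 17 of 19 below), mitochondrial carriers (-0.36) and pectin lyase-like proteins (-0.35; 34 of 50 below).

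A candidate explanation for this order is the length of the coding region, since a short mRNA holds few ribosomes and leaves the heavy fractions sooner when fewer ribosomes are loaded. From general knowledge of the proteins, 20 families were set down as short and 21 as long, and the rest were left out. This sorting was not checked against sequences. The plant invertase/pectin methylesterase inhibitor superfamily was set down as short (-0.11), while the same description ending in "protein" was left out (-0.18). Of the short families 18 had a relative median below 0, and of the long families 19 had one above 0. The median of the short families less that of the long ones was -0.55 on the log2 scale (95% bootstrap interval over families -0.76 to -0.43). The 504 genes of short families went from a median of 35.6% on day 1 to 20.8% on day 8, and the 1023 genes of long families from 38.3% to 31.9%. The exceptions among the short families were histones (0.06) and cupredoxins (0.06), and among the long ones MATE efflux proteins (-0.08) and AMP-dependent synthetases (-0.14). The relative median over genes of short families, -0.28 (-0.35 to -0.20), lay above that of the ribosomal protein list (-0.49), although 4 of the short families were as low as that list. Coding lengths themselves were not used here, the families were sorted on the same data in which the order was seen, and transcript abundance or function may differ between the same families.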
